A study of Homo sapiens with 8 samples.

How the data were processed

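Single-cell RNA was measured in organoids grown from H1 human embryonic stem cells, an established line. The labels give 4 organoid types, esophageal (HEO), gastric (HGO), intestinal (HIO) and colonic (HCO), each at days 18 and 28, with 1 library per type and day. Per the labels, all organoids grew in Matrigel in medium with EGF. HIO and HCO came from mid-hindgut spheroids made with FGF4 and CHIR99021 after activin A. HEO and HGO came from foregut spheroids made with activin A and BMP4, then FGF4 and noggin, with Wnt3a for HEO and CHIR for HGO. Retinoic acid was given on the third of those days in both, and further in the HGO spheroid culture, where HEO received FGF10. The labels give no step that separates HIO from HCO. Cells were freed with trypsin-EDTA. Per the labels' protocols, libraries were made with 10x Genomics chemistry version 3.1, sequenced on a NovaSeq machine and processed with Cell Ranger 2.0.0. Per the submitters' processing notes, the build was hg38 and Seurat 4.3.0.1 was used.

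The deposited matrices hold expected counts, that is estimated, non-whole counts of UMIs per gene and barcode. The step by which the authors made these estimated counts from Cell Ranger output is not given in the sources used here. Between 0.182% and 0.398% of the stored values were whole, and most lay just below a whole number, as after subtraction of a background from UMI counts by a step the labels do not state. Relative to values rounded up to whole UMIs, 4.42% of the counts were missing in HEO at day 18 and 0.817% to 1.53% in the other libraries. The files hold 47707 barcodes, while the design text of the series states 27437 cells, and no filter is stated that links these numbers. No barcode reached 15% mitochondrial counts, as after a filter, though none is given in the sources used here. The largest number of genes per barcode differed between libraries. It was 6001 and 6982 in HEO at days 18 and 28, 7490 and 6009 in HGO, 6996 and 6982 in HIO, and 7461 and 7487 in HCO. Whether upper limits were set per library before deposit is therefore open, and such limits could affect shares and sums. Gene names were as given in the files. A gene missing from a library's list was taken as 0 there. Of 28349 genes listed in any library, 19708 were listed in all 8.

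Barcodes with at least 1000 detected genes and at most 20% mitochondrial counts (13 genes) were kept, which gave 46800. The mitochondrial limit removed none. Scrublet in scanpy 1.11.5 was run per library. Its automatic threshold worked in HCO at day 28 and marked under 0.5% of cells in the other 7 libraries, where the top-scoring 0.8% per 1000 cells were removed instead. Barcodes tied at the limiting score were removed too, so that 2.17% to 7.17% were removed in these 7 libraries. In all, 2636 barcodes were removed as doublets and 44164 cells were analysed. Counts per cell were scaled to 10000 and log-transformed with a pseudocount of 1. The 2000 most variable genes, with library as batch, gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1, with no integration across libraries and seed 1 (python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9, sklearn 1.9.0, matplotlib 3.10.9). Each cluster was named from fixed marker lists of 13 cell classes. A class needed at least 3 of its markers detected in 25% of the cluster's cells, and the class whose markers led was taken. This named 16 of 30 clusters mesenchyme-like. Of 10 clusters with EPCAM and other epithelial markers, 7 got no name because their top 10 genes by fold held more hepatocyte or mesothelium than epithelial markers, such as AFP or UPK1B, which gut epithelium also expresses. All 10 were therefore compared as EPCAM-positive clusters, a choice made after the data were examined.

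Values were summed per library over the mesenchyme-like and over the EPCAM-positive cells, with at least 30 cells per sum, and rounded. Sums were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM, filterByExpr, two-sided, Benjamini-Hochberg threshold 0.05). The region comparison set the 4 hindgut libraries (HIO, HCO) against the 4 foregut libraries (HEO, HGO) with day as covariate and left 5 residual degrees of freedom. Region varies only between organoid types, and this model counts both days of a type as separate libraries. Its p-values may therefore be too small, and the region test of shares has the same limit. The day comparison set day 28 against day 18 with organoid type as covariate, and HCO against HIO and HGO against HEO came from the same model, with 3 residual degrees of freedom. Where a library was left out for the pairs of types, the lone library of its type was assumed to vary like the others. In the day comparison that lone library adds nothing to the day difference. Leaving out either day of a type is then close to leaving out both, so the 8 leave-outs amount to about 4 checks. The region by day term had 4 residual degrees of freedom. The log2 fold changes are HCO minus HIO, HGO minus HEO, hindgut minus foregut and day 28 minus day 18. Their standard errors were derived from the fold change and the F statistic and are approximate. CPM values of named genes use TMM-scaled library sizes, and those of single-library changes and class markers use the plain total of the sum. No fold is given for a gene at 0 in both libraries of a type, and the upper limit for a share of 0 is 3 counts.

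With 1 library per type and day and no statement that cultures were separate, the p-values measure only the spread between these libraries. Protocol, and any batch, cannot be told apart from organoid type. No paired analysis was possible because each group has a single library, apart from the pairing of the 2 days of each organoid type that the design gives. Shares have Clopper-Pearson 95% intervals and single-library CPM exact Poisson 95% intervals. Intervals and floors cover counting error only. Shares were compared with exact permutation tests, two-sided.

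The comparisons, the 24 gene lists, the cell filter, the marker lists and the rule for named genes were fixed before the data were examined. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and adjusted over the lists of a comparison. Of 319 listed genes, 316 were in the files. Named genes were of 2 kinds. The 10 largest each way for region and day and the 5 largest each way for pairs were taken among genes that passed the threshold, reached 50 CPM in at least 1 library and moved the same way without overlap (region), in all 4 types (day) or at both days (pairs). The up to 4 members of each list with the smallest p were named at any level, passing or not. Mitochondrial, ribosomal, clone-named and sex-specific genes were left out. For 2 single libraries, which allow no test, the 3 largest ratios each way with 100 CPM in either were named. Some genes that the rule names are not reported here. Coordinates are from GENCODE 29.

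The alternatives were a stricter filter (2500 genes, 10% mitochondrial), doublets kept, Leiden resolutions 0.5 and 2, each library clustered alone, each library left out, DESeq2 1.42.0 size factors, the DESeq2 Wald test, no low-count filter, sums thinned to the smallest, genes listed in all libraries, and all cells of a library summed. Values rounded up to whole UMIs, and both libraries of a type left out, were added after the data were seen. The tests were run on simulated sums of the same depths with 200 changed genes. These sums varied independently around a common mean per gene, without other differences between organoid types or type-specific changes with time. Recovery in the real data may therefore be lower. Of 4-fold changes, 78% were recovered in the mesenchyme-like region comparison, 95% for day, 67% for HCO against HIO and 68% for HGO against HEO. The EPCAM-positive values were 41%, 94%, 71% and 67%. The region by day term recovered 14% in mesenchyme-like and 0% in EPCAM-positive sums.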

Results

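The data are 8 single-cell RNA libraries, 1 from each of 4 gut organoid types at days 18 and 28. The analysed cells held 52.1 and 53.5 M counts in HEO at days 18 and 28, 98.3 and 28.6 M in HGO, 63.8 and 61.7 M in HIO, and 59.0 and 56.2 M in HCO. HEO gave 5826 and 6027 cells, HGO 7403 and 2392, HIO 7255 and 7471, and HCO 4673 and 3117. Median counts per cell lay between 7003 in HIO at day 18 and 15528 in HCO at day 28. The sums of mesenchyme-like cells held 9.92 to 58.8 M counts. Those of EPCAM-positive cells held 1.48 to 85.0 M, the smallest from 209 HEO cells and 185 HIO cells at day 28.

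Cells with collagen and fibroblast markers (mesenchyme-like) and EPCAM-positive cells made up most cells of each library, in very different proportions. Mesenchyme-like cells were 86.0% (95% interval 85.1 to 86.9) of HEO cells at day 18 and 89.96% (89.2 to 90.7) at day 28. In HIO they were 81.9% (81.0 to 82.8) and 96.6% (96.1 to 97.0). HGO held 16.6% (15.8 to 17.5) at day 18 and 71.1% (69.2 to 72.9) at day 28. HCO held 24.5% (23.2 to 25.7) and 43.7% (41.9 to 45.5). EPCAM-positive cells were 76.2% of HGO and 75.3% of HCO cells at day 18 and 28.1% and 55.6% at day 28, against 2.48% to 15.7% in HEO and HIO. Cardiac or skeletal muscle-like cells were found in HEO, at 3.60% (3.14 to 4.12) and 5.13% (4.58 to 5.71), and otherwise as 2 cells of HCO at day 28. The 10 leading genes of their cluster were ACTC1, TTN, MYLPF, NEB, MYH3, KLHL41, TNNT1, MYL1, TNNI1 and TNNC2. Cartilage-like cells were found in the 4 foregut libraries, from 0.292% in HEO to 7.19% in HGO, both at day 18, and were 0 in the hindgut libraries. Endothelium-like cells reached 2.44% in HIO at day 18 and were 0 in HGO, where 0 of 7403 cells at day 18 allows a share of up to 0.0405%. No cluster was named neuron, neural progenitor, neural crest or glia, immune, pluripotent, endocrine, hepatocyte or mesothelium. EPCAM stood at 0.804 to 3.43 CPM in mesenchyme-like sums and 108 to 668 CPM in EPCAM-positive sums.

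**Figure D1:**
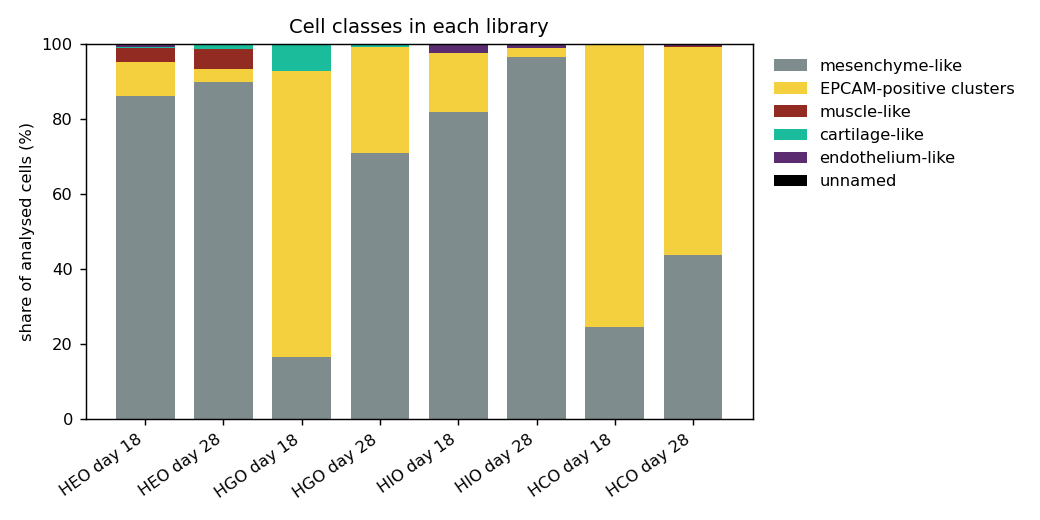
Stacked bars give the share of analysed cells (%) in each cell class for the 8 libraries. Mesenchyme-like cells range from 16.6% in HGO at day 18 to 96.6% in HIO at day 28.

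The mesenchyme-like share was higher at day 28 than at day 18 in 4 of 4 organoid types. The differences were 3.92 points in HEO, 54.5 in HGO, 14.7 in HIO and 19.2 in HCO, with a mean of 23.1 points (SD 21.9, n = 4 pairs). The exact two-sided sign permutation test gave p = 0.125, the smallest value that 4 pairs allow. The EPCAM-positive share moved the other way in all 4 types, with a mean difference of -21.7 points (SD 18.5). Without either HGO library the mean mesenchyme-like difference was 12.6 points. Foregut and hindgut shares were not separable. They averaged 65.9% ± 33.9 and 61.6% ± 33.3 (SD, n = 4 each), a hindgut minus foregut difference of -4.28 points (exact permutation p = 0.914, smallest possible 0.0286). That difference was positive without HEO at day 18 (2.43) or day 28 (3.74) and without HCO at day 18 (8.12) or day 28 (1.71). It was -20.7 without HGO at day 18, -11.0 without HIO at day 18, -15.9 without HIO at day 28 and -2.56 without HGO at day 28.

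The region comparison asked how mesenchyme-like cells of foregut organoids differ from those of hindgut organoids. Different clusters held most of these cells, clusters 1, 5 and 10 in HEO, 5, 11 and 13 in HGO, 15, 17, 18 and 26 in HIO and 12 in HCO. HAND2, a transcription factor of gut mesenchyme, was higher in all 4 hindgut libraries (79.0 ± 12.9 CPM) than in the 4 foregut libraries (4.67 ± 3.35, mean ± SD, n = 4 each), a log2 fold change of 4.16 ± 0.50 (SE, adjusted p = 0.0121). The secreted glycoprotein gene LGALS3BP differed by 3.95 ± 0.30 (39.9 ± 16.6 against 2.68 ± 1.64 CPM) and LUM, which encodes the collagen-binding proteoglycan lumican, by 2.78 ± 0.28 (2940 ± 563 against 430 ± 185 CPM). In the foregut direction, MIA, a gene known from melanoma and cartilage, stood at 39.8 ± 14.0 against 0.223 ± 0.181 CPM, a log2 fold change of -7.78 ± 0.60. S100B, known from glia and cartilage, OLFML2B and the WNT amplifier RSPO3 fell by 7.08 ± 0.70, 3.98 ± 0.34 and 2.86 ± 0.35 on the log2 scale. These 7 genes passed in every leave-out of 1 library, with adjusted p between 0.00479 and 0.0123 in the full fit. Cartilage-like cells, which are not part of these sums, occurred in the foregut libraries only. Some cartilage markers were still detected in the sums. Mesenchyme-like cluster 2 had 4 of 8 of them. S100B, in the fixed lists a marker of neural crest or glia, was among its leading genes. Of its 1001 cells, 457 and 525 came from HEO at days 18 and 28, and 8 and 11 from HGO. Whether cluster 2 carries the MIA or S100B difference was not tested. HAND2 lies on chromosome 4 (173524969 to 173530229), LUM on chromosome 12 (91102629 to 91111831) and MIA on chromosome 19 (40771648 to 40777490), all in GRCh38.

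In total 306 genes were higher in hindgut and 311 in foregut mesenchyme-like sums, of 17599 tested in the 4 against 4 libraries (edgeR). These are HIO and HCO against HEO and HGO, with both days of a type counted as separate libraries. DESeq2 called 1148 and 1048. The edgeR total of 617 was 124 without HEO at day 18, 166 without HEO at day 28, 119 without HGO at day 18, 364 without HIO at day 18, 144 without HIO at day 28 and 118 without HCO at day 28. It was 46, 354, 968 and 377 without both HEO, HGO, HIO or HCO libraries, and 1 when all cells of a library were summed.

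**Figure D2:**
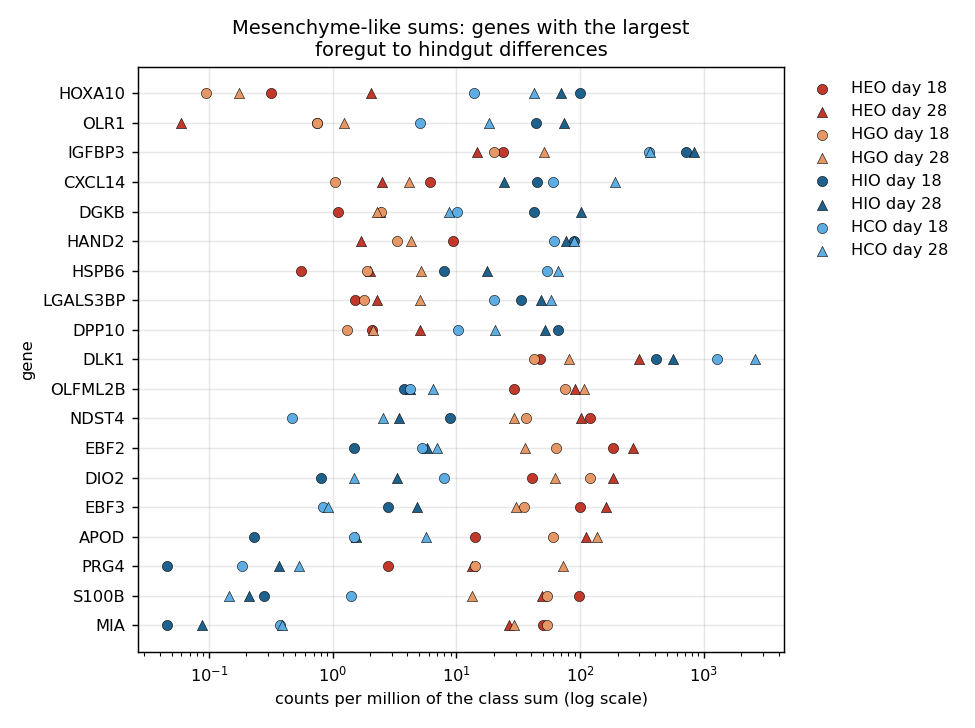
Dots give CPM of the mesenchyme-like sum (log axis) in each library for genes with the largest region differences, colours mark organoid type, circles day 18 and triangles day 28. MIA lies at 26.3 CPM or more in the 4 foregut libraries and at 0.387 or less in the 4 hindgut libraries.

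Posterior HOX genes, which mark posterior position along the body axis, were higher in hindgut mesenchyme. Of 7 tested members of HOX groups 10 to 13, 6 were higher in the hindgut and 0 in the foregut, and all 7 passed when adjusted over the list alone. HOXA10 (chromosome 7, 27170591 to 27180261) stood at 56.3 ± 36.6 CPM in hindgut and 0.657 ± 0.926 in foregut sums (n = 4 each), a log2 fold change of 6.38 ± 1.00 (SE, adjusted p = 0.024), and HOXC10 differed by 6.65 ± 1.00. The list test gave an adjusted p of 6.67e-12, and adjusted p = 0.17 with an estimated correlation. Of 12 members of HOX groups 6 to 9, 4 were higher (HOXA9, HOXB9, HOXC8 and HOXC9) and 8 when adjusted over the list alone (adjusted p = 1.42e-10, and adjusted p = 0.346 with an estimated correlation). None of 13 members of HOX groups 1 to 5 passed in either direction (edgeR, list test adjusted p = 0.449). The HOXA10 call ended without HEO at day 18 (adjusted p = 0.0847), HGO at day 18 (0.0801), HIO at day 28 (0.064) or HCO at day 28 (0.0612). The HOXC10 call ended without any of these or HEO at day 28 (0.0584 to 0.0763), as did HOXA9 and HOXC9 (0.0609 to 0.0814). HOXB9 kept its call without HGO or HCO at day 18 and HOXC8 without HGO at day 28 or HCO at day 18, and both lost it in the other leave-outs (0.0525 to 0.133).

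Smooth muscle, matrix, niche factor and pericyte lists were tested next. Of 14 smooth muscle genes, 2 were higher, enteric actin ACTG2 (3.24 ± 0.46) and MYOCD, the master coactivator of the smooth muscle program (3.60 ± 0.60). Adjusted over the list alone there were 6 (list adjusted p = 4.25e-07, and adjusted p = 0.346 with an estimated correlation). Of 20 interstitial collagen matrix genes, LUM, COL3A1 (1.35 ± 0.28) and MMP2 (1.16 ± 0.20) were higher and COL12A1 lower (-3.27 ± 0.55). Adjusted over the list alone, 11 were higher and 1 lower (list adjusted p = 9.21e-06, and adjusted p = 0.489 with an estimated correlation). Of 14 epithelial niche factors, the growth factor genes FGF7 (2.74 ± 0.43) and IGF2 (1.72 ± 0.30) were higher and RSPO3 lower. BMP4 differed by 2.40 ± 0.37, while the BMP target ID1 differed by -1.43 ± 0.21. Of 9 pericyte genes, ABCC9 (-1.97 ± 0.27) and NDUFA4L2 (-2.39 ± 0.45) were lower (list adjusted p = 0.0384, and adjusted p = 0.498 with an estimated correlation). The insulin-like growth factor binding protein gene IGFBP3 differed by 4.41 ± 0.51. Single calls here ended in leave-outs. ABCC9 was lost without HGO at day 18 (adjusted p = 0.0615), IGFBP3 without HGO at day 18 (0.0512), ACTG2 without HEO at day 18 (0.0589) or day 28 (0.0644), and ID1 without HEO at day 18 (0.0604), HEO at day 28 (0.0644) or HGO at day 18 (0.0695). FGF7 was lost without HEO at day 18 (0.0791), HIO at day 28 (0.0551) or HCO at day 28 (0.0641), and BMP4 and MYOCD without either HEO library, HGO at day 18, HIO at day 28 or HCO at day 28 (0.0525 to 0.0963). COL3A1 and COL12A1 kept their calls without HGO at day 28, MMP2 and NDUFA4L2 without HIO at day 18 and IGF2 without HGO or HIO at day 28. They lost them in the other leave-outs (0.0526 to 0.134).

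The other lists had few members past the threshold in the mesenchyme-like region comparison. Of 11 WNT response genes, the secreted antagonist WIF1 was lower in hindgut (list adjusted p = 0.00375, and adjusted p = 0.428 with an estimated correlation). The remaining list tests did not pass. TBX3 was higher among 11 foregut mesenchyme transcription factors (list adjusted p = 0.449), BMP4 and CXCL14 among 12 subepithelial mesenchyme genes (0.294) and NID1 among 15 basement membrane genes (0.125). Of 12 hedgehog response genes BOC was lower (0.449), and of 13 BMP response genes ID1 (0.349). None of 11 retinoic acid genes (0.0833), 14 angiogenic factors (0.329) or 15 glycolysis and hypoxia genes (0.449) passed in edgeR. WIF1 was lost without HIO at day 18 (0.0547) or HCO at day 28 (0.0514), BOC without either HEO library, HGO at day 18, HIO at day 28 or HCO at day 28 (0.0501 to 0.0641), TBX3 and NID1 without any library but HGO at day 28 (0.0526 to 0.114), and CXCL14 without any of the 8 (0.0518 to 0.115).

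The day comparison asked what changed in mesenchyme-like cells between days 18 and 28 across the 4 types. In 3 of the types other clusters led the class at day 28 than at day 18. In HEO cluster 1 was 49.9% of cells at day 18 and 4.53% at day 28, while cluster 10, with SFRP2 among its leading genes, was 1.75% and 61.1%. In HGO cluster 11 led at day 18 (6.88%) and cluster 13 at day 28 (51.0%, against 3.54% at day 18), while in HIO cluster 17 led at day 18 (23.0%, and 21.7% at day 28) and cluster 18 at day 28 (24.9%, against 0.772% at day 18), and cluster 15 was 22.6% and 6.71%. In HCO cluster 12 led at both days (914 of 1143 and 1091 of 1362 mesenchyme-like cells). SFRP2, a secreted WNT modulator, rose in 4 of 4 types by 2.67 ± 0.12 on the log2 scale (SE, adjusted p = 0.00534), from 62.4 to 435 CPM in HEO, 1.88 to 9.89 in HGO, 9.93 to 73.8 in HIO and 20.9 to 114 in HCO. PRG4, which encodes the lubricating proteoglycan lubricin, rose by 2.31 ± 0.17, and LIX1 fell by 3.32 ± 0.23 (both adjusted p = 0.0366). PRTG, a cell surface gene of early embryonic development, fell by 1.13 ± 0.10 (adjusted p = 0.0461). The neurotrophic factor receptor CNTFR, higher by 1.75, and BCL11B and NETO2, at -2.27 and -1.17, were called outside the naming rule and chosen after their values were seen, as were 2 clone-named genes. SFRP2 lies on chromosome 4 (153780592 to 153789120, GRCh38).

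That made 5 genes higher and 4 lower of 17599 (edgeR, 8 libraries), with 3393 at an unadjusted p under 0.05, and DESeq2 called 584 and 545. The SFRP2 call ended without HEO at day 18 (adjusted p = 0.0728) or day 28 (0.067), PRG4 without HEO, HGO or HCO at either day (0.0585 to 0.22), LIX1 without HEO, HIO or HCO at either day (0.06 to 0.0728) and PRTG without any of the 8 libraries (0.0715 to 0.174). The total of 9 became 0 without HEO at day 18 or 28, 2 without HGO at either day, 14 without HIO at either day and 1 without HCO at either day.

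Lists of proliferation, matrix and stress genes were tested between the days. None of 15 genes of the G2 and M phases passed over all genes, but 14 were lower when adjusted over the list alone (median log2 fold change -0.63, list adjusted p = 1.09e-15, and adjusted p = 0.311 with an estimated correlation). For the S phase list these were 0 and 10 of 15 (median -0.33, 3.39e-07, and adjusted p = 0.412 with an estimated correlation). For interstitial collagen matrix they were 0 and 12 of 20, in the day 28 direction (median 0.78, 9.19e-15, and adjusted p = 0.311 with an estimated correlation). Immediate early and heat shock genes, which dissociation can induce, passed for 0 and 5 of 14 (median 0.58, 0.000118, and adjusted p = 0.387 with an estimated correlation). A higher mesenchyme-like share accompanied day 28 in each type.

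The comparison of HCO with HIO asked how the mesenchyme of the hindgut-derived types differed. These cells lay mainly in clusters 15, 17, 18 and 26 in HIO and in cluster 12 in HCO. ATF3, a stress-induced transcription factor, was higher in HCO (22.5 and 37.2 CPM at days 18 and 28) than in HIO (0.765 and 1.06), a log2 fold change of 5.01 ± 0.26 (SE, adjusted p = 0.0109, 2 libraries each), and passed in every leave-out. The matrix gene TNC was higher by 2.68 ± 0.29 and the WNT amplifier RSPO2 by 2.78 ± 0.25. GATA4, a transcription factor of endoderm and heart, stood at 40.9 and 21.7 CPM in HCO against 1.85 and 0.904 in HIO (4.51 ± 0.55). Lower in HCO were WNT5A (-2.89 ± 0.35), MAB21L2 (-5.69 ± 0.72) and the cartilage collagen COL2A1 (-4.60 ± 0.58). The retinoic acid synthesis gene ALDH1A1 (-4.72 ± 0.76) and the retinoic acid degrading enzyme CYP26B1 (-4.21 ± 0.53) were also lower. SLN, a regulator of the muscle calcium pump, was at 97.9 and 1.69 CPM in HCO and 0 in HIO. ATF3 lies on chromosome 1 (212565334 to 212620777, GRCh38).

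The lists were then compared between HCO and HIO mesenchyme. Of 15 S phase genes, 9 were lower in HCO, with RRM1 at -0.69 ± 0.12 and GINS2 at -0.98 ± 0.15, and 15 adjusted over the list alone (list adjusted p = 1.3e-09). Of 15 G2 and M genes, AURKB, BUB1, CDK1 and TOP2A (-1.05 ± 0.20) were lower, and 14 adjusted over the list alone (9.88e-08). Of 14 dissociation stress genes, 5 were higher, such as ATF3 and IER3 (2.03 ± 0.28), and 10 adjusted over the list alone (2.52e-07). Of 14 epithelial niche factors, 5 were higher, RSPO2, HGF (2.72 ± 0.55), IGF1 (4.47 ± 0.77), SFRP1 (1.67 ± 0.26) and SFRP2 (0.83 ± 0.15), and 8 with 1 lower adjusted over the list alone (8.01e-05). Of 13 BMP response genes, 6 were higher, such as BAMBI (1.68 ± 0.21), and 1 lower, SMAD9 (-1.24 ± 0.17), or 8 and 2 adjusted over the list alone (0.00052). Of 20 collagen matrix genes, COL6A3, FN1, LOX and TNC were higher, and 11 over the list alone (4.38e-06). Of 13 genes of HOX groups 1 to 5, HOXB3 (-1.56 ± 0.19) and HOXB5 (-1.63 ± 0.19) were lower and 10 adjusted over the list alone (5.63e-08). Each of these list calls was lost at adjusted p = 0.309 with an estimated correlation. The retinoic acid list had 3 of 11 lower, ALDH1A1, CRABP1 and CYP26B1, and none higher, with a median of 0.20 against a mean of -0.82 and a downward test that did not pass (adjusted p = 0.185).

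In total 757 genes were higher in HCO and 550 in HIO of 19217 (edgeR), and DESeq2 called 1629 and 1127. The total of 1307 was 471 without HGO at day 18, 479 without HGO at day 28, 7 without HIO at day 18, 99 without HIO at day 28, 113 without HCO at day 18 and 788 without HCO at day 28. Among the genes above, the TNC call ended without HIO at day 18 (adjusted p = 0.0839), COL2A1 without HCO at day 18 (0.129), RSPO2 without HIO at day 18 (0.0758) or day 28 (0.0557), MAB21L2 without HIO at day 18 (0.0888) or day 28 (0.0649), and WNT5A and CYP26B1 without HIO at day 18 (0.0736 and 0.084) or HCO at day 18 (0.0963 and 0.0855). GATA4, ALDH1A1, SLN, HOXB3, HOXB5, BAMBI, SMAD9 and COL6A3 were lost without HCO at day 18 or either HIO library (0.0552 to 0.145), and IER3 without HIO at day 18 or either HCO library (0.0558 to 0.0945). GINS2, TOP2A, IGF1, SFRP1, FN1 and LOX were lost without HCO at day 18 or any HGO or HIO library (0.0515 to 0.223), and RRM1, SFRP2, AURKB and CDK1 without any of these or HCO at day 28 (0.0538 to 0.248). HGF was lost without HCO at day 18 or any HEO or HIO library (0.0511 to 0.208), CRABP1 without any HEO, HIO or HCO library (0.0511 to 0.197) and BUB1 without any of the 8 (0.0506 to 0.241). With DESeq2 size factors in edgeR, BUB1 (0.0508) and CDK1 (0.0507) were not called.

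The comparison of HGO with HEO asked how the mesenchyme of the foregut-derived types differed, and anterior HOX genes led it. These cells lay mainly in clusters 1, 5 and 10 in HEO and 5, 11 and 13 in HGO. HOXB5 (chromosome 17, 48591257 to 48593961, GRCh38) stood at 26.0 and 22.2 CPM in HGO and 0.191 and 0.259 in HEO at days 18 and 28, a log2 fold change of 6.72 ± 0.25 (SE, adjusted p = 0.000801, 2 libraries each). HOXB4 differed by 5.09 ± 0.28 and HOXB3 by 4.07 ± 0.21, and all 3 passed in every leave-out. The annotated span of HOXB3 (48548870 to 48604912) covers HOXB4 and HOXB5, so the split of reads among them is uncertain. Of 13 members of HOX groups 1 to 5, 9 were higher in HGO, and 13 adjusted over the list alone (list adjusted p = 5.6e-72). Of 61 list calls over the comparisons other than the region by day term, this was the 1 that held with an estimated correlation (adjusted p = 0.0445). HOXA3, on chromosome 7 (27106184 to 27152581), differed by 7.07 ± 0.66, with 66.4 and 65.5 CPM in HGO against 0.423 and 0.578 in HEO. Of 12 members of groups 6 to 9, HOXB6 and HOXB7 were higher, and 5 adjusted over the list alone (5.12e-11, and adjusted p = 0.312 with an estimated correlation). None of 9 members of groups 10 to 13 passed (edgeR, list adjusted p = 0.0467 in the HEO direction, and adjusted p = 0.51 with an estimated correlation).

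**Figure D3:**
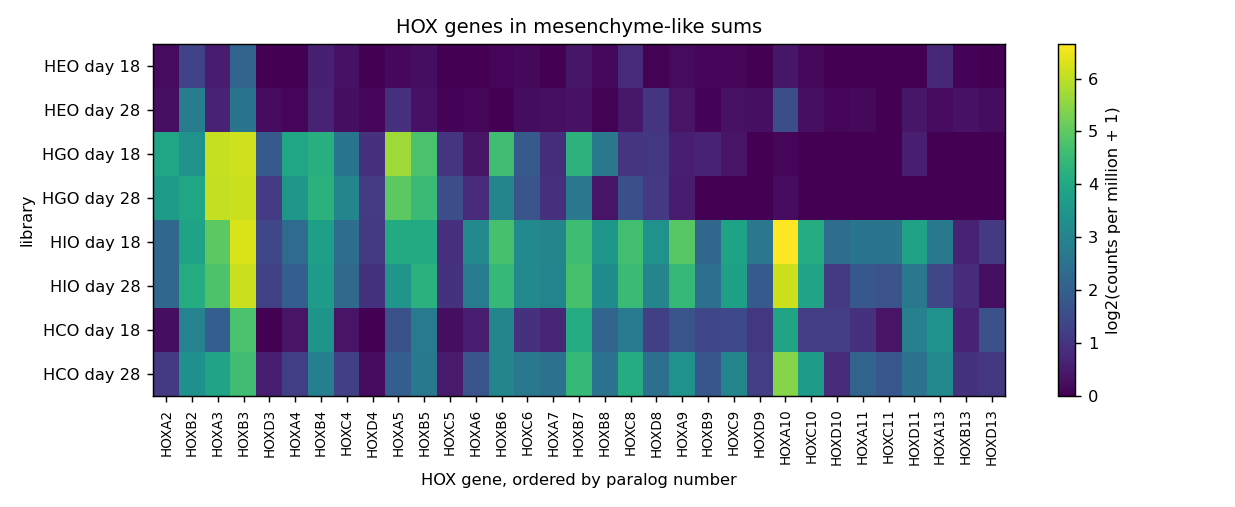
The heat map gives log2(CPM + 1) of HOX genes, ordered by paralog number, in the mesenchyme-like sum of each library. Groups 1 to 5 are low in HEO and higher in HGO, with HOXA3 at 66.4 and 0.423 CPM at day 18.

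Other genes separated HGO from HEO mesenchyme. Cardiac actin ACTC1 was higher in HGO by 7.23 ± 0.46 and PLAC9 by 4.17 ± 0.23, and SFRP2 was lower by -5.31 ± 0.19, at 62.5 and 433 CPM in HEO and 1.88 and 9.88 in HGO. These 3 passed in every leave-out (adjusted p = 0.00729, 0.004 and 0.000801 in the full fit). NR1H4, which encodes the bile acid receptor FXR, was at 10.3 and 55.8 CPM in HGO and 0 in HEO. Of 14 smooth muscle genes, ACTC1 and MYLK (2.13 ± 0.27) were higher, and 5 adjusted over the list alone (2.12e-13, and adjusted p = 0.126 with an estimated correlation). Of 12 hedgehog response genes, the coreceptors CDON (-2.10 ± 0.25) and GAS1 (-3.77 ± 0.51) were lower. Adjusted over the list alone, 7 were higher and 4 lower. The retinoic acid synthesis gene ALDH1A2 was lower by -4.55 ± 0.60. Cardiac or skeletal muscle-like cells, which are not part of these sums, were found in HEO and not in HGO.

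In total 84 genes were higher in HGO and 73 in HEO of 19217 (edgeR), and DESeq2 called 554 and 385. The total of 157 was 16 without HEO at day 28, 47 without HGO at day 18, 18 without HGO at day 28, 99 without HIO at either day and 241 without HCO at day 18. It was 385 with no low-count filter, 261 with each library clustered alone and 3065 with all cells summed. The HOXA3 call ended without HEO at day 18 (adjusted p = 0.0565) or day 28 (0.0912) and without HGO at day 18 (0.0566) or day 28 (0.0763). NR1H4 was lost without HEO at day 28 (0.0822), and CDON without HEO at day 28 (0.0912), HGO at day 18 (0.111) or HGO at day 28 (0.233). ALDH1A2 was lost without either HEO or HGO library (0.0716 to 0.204), MYLK and GAS1 without HEO at day 28 or any HGO or HIO library (0.0549 to 0.287), HOXB6 without HEO at day 28 (0.0752) and HOXB7 without either HEO or HIO library (0.0538 to 0.135).

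Whether the change with time differed between foregut and hindgut was tested by the region by day term. In mesenchyme-like sums 0 of 17599 genes passed (edgeR), with 130 at an unadjusted p under 0.05, and DESeq2 called 1. In EPCAM-positive sums 0 of 15258 passed, with 27 unadjusted and 1 by DESeq2. In mesenchyme-like sums the G2 and M list had an adjusted p of 4.37e-08 with a median hindgut minus foregut difference in day change of 0.54, and adjusted p = 0.687 with an estimated correlation. A median of -0.61 for collagen matrix genes gave 4.76e-05, and adjusted p = 0.687 with an estimated correlation. On simulated data this term recovered 14% of 4-fold changes in mesenchyme-like sums and 0% in EPCAM-positive sums.

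In EPCAM-positive cells the region comparison found few genes. Different clusters held most of these cells, cluster 3 in HEO, 14, 19 and 22 in HGO, 27 in HIO and 16, 20 and 30 in HCO. CFTR, the chloride channel gene mutated in cystic fibrosis (chromosome 7, 117465784 to 117715971, GRCh38), stood at 48.4 ± 23.0 CPM in hindgut and 1.25 ± 0.891 in foregut sums (mean ± SD, n = 4 each), a log2 fold change of 5.64 ± 0.50 (SE, adjusted p = 0.0397). MALL, a membrane protein gene on chromosome 2 (110083870 to 110116566), stood at 73.8 ± 7.65 against 2.27 ± 1.505 CPM (5.33 ± 0.48). EMP1 differed by 2.46 ± 0.22 (181 ± 51.1 against 35.6 ± 18.3 CPM) and PROX1, a homeobox gene, by 2.30 ± 0.25 (89.7 ± 24.7 against 18.3 ± 2.93 CPM). NLGN1, a synaptic adhesion gene, was the gene called higher in foregut (-3.67). It was chosen after its value was seen, being outside the naming rule. Of 13 tested small intestinal genes, 0 passed over all genes and 8 were higher in hindgut adjusted over the list alone (list adjusted p = 1.67e-13, and adjusted p = 0.196 with an estimated correlation). For 8 colonic genes these were 0 and 2 (0.000274, and adjusted p = 0.126 with an estimated correlation). None of 6 esophageal genes passed over all genes in edgeR, with a list test in the foregut direction (0.0317, and adjusted p = 0.651 with an estimated correlation).

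That made 8 genes higher in hindgut and 1 in foregut of 15258 (edgeR, 8 libraries), with 2083 at an unadjusted p under 0.05, and DESeq2 called 475 and 293. The total of 9 was 0 without HEO at day 18, HIO at day 18, HIO at day 28 or HCO at day 28, 1 without HEO or HGO at day 28 and 2 without HGO or HCO at day 18. It was 2341 without both HGO libraries, 0 without both HIO libraries, and 0 at resolution 2 or with each library clustered alone. The CFTR call ended without any library but HCO at day 18 (adjusted p = 0.0899 to 0.157), MALL without any but HGO at day 18 (0.0858 to 0.157), and EMP1 (0.101 to 0.157) and PROX1 (0.0557 to 0.195) without any of the 8.

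In EPCAM-positive cells days 18 and 28 were compared in the same way. Cluster 3 in HEO and cluster 27 in HIO held most of these cells at both days. The make-up in HIO still shifted, with 1095 of 1138 cells at day 18 and 147 of 185 at day 28 in cluster 27, and 13 and 33 in cluster 16. In HGO clusters 14, 19 and 22 were 31.99%, 23.7% and 18.9% of cells at day 18 and 19.6%, 4.43% and 2.01% at day 28. In HCO cluster 16 was 13.1% and 24.8%, and cluster 30 was 16.3% and 5.58%. The chromatin gene HMGB3 fell by 1.11 ± 0.10 on the log2 scale (SE, adjusted p = 0.0282) and the thymosin gene TMSB15A by 1.20 ± 0.12 (adjusted p = 0.0358), each in 4 of 4 types. The mitotic genes DLGAP5 (-1.35 ± 0.18), HMMR (-1.29 ± 0.19) and CENPF (-1.15 ± 0.16) fell at adjusted p = 0.0489. Of 15 G2 and M genes, CENPF, HMMR and AURKA (-1.17 ± 0.18) fell, and 15 were lower adjusted over the list alone (median -1.16, list adjusted p = 3.11e-26). For the S phase list these were 0 and 14 of 15 (2.17e-13), and both list calls were lost at adjusted p = 0.237 with an estimated correlation. OLFM4, a marker of intestinal stem cells, rose by 3.73 ± 0.44 (adjusted p = 0.0457), from 1.78 to 61.2 CPM in HGO, 2.79 to 30.2 in HIO and 35.7 to 243 in HCO. In HEO it was 0.153 and 0.54 CPM, under 3 counts in each sum, so no rise can be read there. AREG, which encodes the growth factor amphiregulin, rose by 3.12 ± 0.47 and the chemokine gene CXCL1 by 2.11 ± 0.28. The glucose transporter SLC2A1 (0.95 ± 0.12) and PFKFB3 (1.05 ± 0.15) rose among 16 glycolysis and hypoxia genes, and 6 did adjusted over the list alone (2.84e-06, and adjusted p = 0.351 with an estimated correlation). JUN (1.23 ± 0.18) rose among 14 dissociation stress genes, and 12 were higher and 1 lower adjusted over the list alone (2.78e-14, and adjusted p = 0.237 with an estimated correlation).

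DCN, a fibroblast proteoglycan gene, was also called higher at day 28 in EPCAM-positive sums (1.79 ± 0.27). Its levels there were 44.5 and 165 CPM in HEO and 14.98 and 63.9 in HIO at days 18 and 28, and 2.87 or less in HGO and HCO, while in mesenchyme-like sums it was 143 to 2341 CPM. The fibroblast collagen genes COL1A2 (1.30 ± 0.11, adjusted p = 0.0282) and COL1A1 (0.91 ± 0.12, adjusted p = 0.0489) were called higher as well, outside the naming rule and chosen after their values were seen. COL1A1 stood at 67.1 and 117 CPM in HEO, 32.96 and 69.3 in HIO and 9.69 or less in HGO and HCO. In total 58 genes rose and 36 fell of 15258 (edgeR), and DESeq2 called 499 and 506. The total of 94 was 4 without HEO at day 18, 2 without HEO at day 28, 11 and 16 without HGO at days 18 and 28, 1 without HIO at either day, and 274 and 313 without HCO at days 18 and 28. It was 0 under the stricter cell filter or with each library clustered alone, 5 with doublets kept and 2 with all cells summed. All 23 named calls of this comparison ended without HEO at day 18 (adjusted p = 0.0552 to 0.0916) or day 28 (0.0574 to 0.0919) and without HIO at day 18 (0.138 to 0.204) or day 28 (0.135 to 0.201), and 21 and 20 of them without HGO at days 18 and 28 (0.063 to 0.209). PFKFB3 was also lost without HCO at day 18 (0.0508), and BHLHE41 without HCO at day 28 (0.0653).

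In EPCAM-positive cells of HCO and HIO, 10 of 15 small intestinal genes were lower in HCO and 0 higher, with the same count adjusted over the list alone (list adjusted p = 9.69e-08, and adjusted p = 0.308 with an estimated correlation). APOC3 (-10.59 ± 0.55, SE, adjusted p = 0.000425), APOA4 (-9.62 ± 0.56) and APOA1 (-5.58 ± 0.75), which encode apolipoproteins, were lower in HCO, as were the fatty acid binding protein gene FABP2 (-4.92 ± 0.24) and the retinol binding protein gene RBP2 (-5.60 ± 0.71). APOA4 stood at 317 and 1075 CPM in HIO at days 18 and 28 and at 0.132 and 2.03 in HCO. APOA4 lies on chromosome 11 (116820700 to 116823306) and FABP2 on chromosome 4 (119317250 to 119322390, GRCh38). Higher in HCO were the WNT antagonist DKK1 (5.17 ± 0.53) and the secreted protease inhibitor WFDC2 (2.72 ± 0.35). FABP4, the adipocyte fatty acid binding protein gene, was at 188 and 131 CPM in HCO and 0 in HIO. These 8 genes passed in every leave-out. Different clusters held the cells compared. Cluster 27, with APOA1 and APOA4 among its leading genes, held 1095 of 1138 HIO cells at day 18 and 147 of 185 at day 28. Clusters 16, 20 and 30 held most in HCO. Cluster 30, with FABP4 and the keratin gene KRT13 among its leading genes, was 16.3% and 5.58% of HCO cells and held 0 and 2 HIO cells.

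Esophageal, HOX and other lists were compared between the EPCAM-positive sums of HCO and HIO. Of 12 esophageal genes, 6 were higher and 0 lower, with the same count adjusted over the list alone (list adjusted p = 0.000286, and adjusted p = 0.308 with an estimated correlation). Among them were TP63, a master gene of stratified epithelium, at 8.17 and 8.78 CPM against 0 in HIO, and SOX2 (4.66 ± 0.40). The cornified envelope gene SPRR3 was at 75.01 and 21.8 CPM in HCO and 0 in HIO. Cluster 30, mostly HCO cells, had KRT7 and UPK1B among its leading genes beside KRT13, a member of this list. The list genes therefore do not by themselves identify esophageal cells. Of 5 tested members of HOX groups 10 to 13, 4 were higher, and 5 adjusted over the list alone (0.000286, and adjusted p = 0.464 with an estimated correlation). HOXA10 differed by 1.95 ± 0.50. DESeq2 did not share 13 of the 52 calls that the naming rule gave in this comparison. Of the genes given here, these were HOXA10 (adjusted p = 0.0916), HOXA13 (0.294), HOXD11 (0.481), HOXD13 (0.323), HOXA3 (0.0584) and HOXB5 (0.0653). Of 9 members of groups 6 to 9, HOXB6, HOXB8, HOXB9 and HOXB7 (5.59 ± 0.46) were higher and HOXC9 lower, or 5 and 2 adjusted over the list alone (0.00652, and adjusted p = 0.311 with an estimated correlation). Groups 1 to 5 gave 4 of 9 higher, such as HOXB3 and HOXB5, and 6 over the list alone (0.00199, and adjusted p = 0.311 with an estimated correlation). Of 9 colonic genes, 2 were higher, such as WFDC2, and CA2 (-1.59 ± 0.22), CA4, SLC26A3 and CEACAM6 lower, with a median of -0.73, a mean of 0.03 and a downward test that did not pass (adjusted p = 0.212). CEACAM6 and HOXC9 were outside the naming rule and chosen after their values were seen. Of 16 glycolysis and hypoxia genes, NDRG1, PFKFB4, SLC2A1 and LDHA (-1.19 ± 0.23) were lower, and 8 over the list alone (0.000237, and adjusted p = 0.464 with an estimated correlation). The collagen gene COL3A1 stood at 158 and 298 CPM in the EPCAM-positive sums of HIO and at 23.2 and 11.5 in those of HCO.

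In total 1124 genes were higher in HCO and 1212 in HIO of 17613 (edgeR, 2 libraries each), and DESeq2 called 1413 and 1600. The total of 2336 was 204 without HIO at day 18, 927 without HIO at day 28 and 1375 without HCO at day 18, and 1173 with each library clustered alone. Without HIO at day 18 the calls ended for TP63 (adjusted p = 0.142), SOX2 (0.0588), SPRR3 (0.221) and HOXB7 (0.0698). HOXA10 was lost without HIO at day 18 (0.56) or HCO at day 18 (0.573), and LDHA without HIO at day 18 (0.149) or day 28 (0.0631). HOXA13, HOXD11, HOXD13, HOXB9 and PFKFB4 were lost without HIO or HCO at day 18 (0.0507 to 0.479), and HOXB3, HOXB5, HOXB8 and NDRG1 without these or HIO at day 28 (0.0507 to 0.388). HOXA3 was lost without these 3 or HGO at day 18 (0.0672 to 0.514), HOXB6 without HIO at day 18 (0.0968), SLC2A1 without either HIO or HCO library (0.0769 to 0.192), CA4 without HIO or HCO at day 28 (0.159 and 0.0866) and SLC26A3 without HIO at day 18 (0.2) or day 28 (0.109).

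EPCAM-positive cells of HGO and HEO differed along gastric and esophageal marker genes. They lay mainly in clusters 14, 19 and 22 in HGO and in cluster 3 in HEO. Of 11 gastric genes, 11 were higher in HGO, with the same count adjusted over the list alone (list adjusted p = 2.63e-07, and adjusted p = 0.23 with an estimated correlation). The tight junction gene CLDN18 (chromosome 3, 137998735 to 138033655, GRCh38) stood at 1748 and 1057 CPM in HGO and 21.6 and 0.508 in HEO, a log2 fold change of 6.86 ± 0.63 (SE, adjusted p = 0.000215). The gastric protease CTSE (7.31 ± 0.72), the gastric surface mucin MUC5AC (7.99 ± 0.89) and VSIG1 (7.16 ± 0.67) followed. Of 12 esophageal genes, 9 were lower in HGO and 0 higher, and 10 were lower adjusted over the list alone (6.69e-06, and adjusted p = 0.197 with an estimated correlation). The basal keratin KRT5 (chromosome 12, 52514575 to 52520687) stood at 29.6 and 261 CPM in HEO and 0.314 and 7.16 in HGO (-5.76 ± 0.36). PAX9 (-6.75 ± 0.38), TP63 (-4.17 ± 0.47) and SOX2 (-1.82 ± 0.19) were lower too. BPIFA1, an airway secretory gene, was at 13.9 and 1998 CPM in HEO and 0 in HGO.

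**Figure D4:**
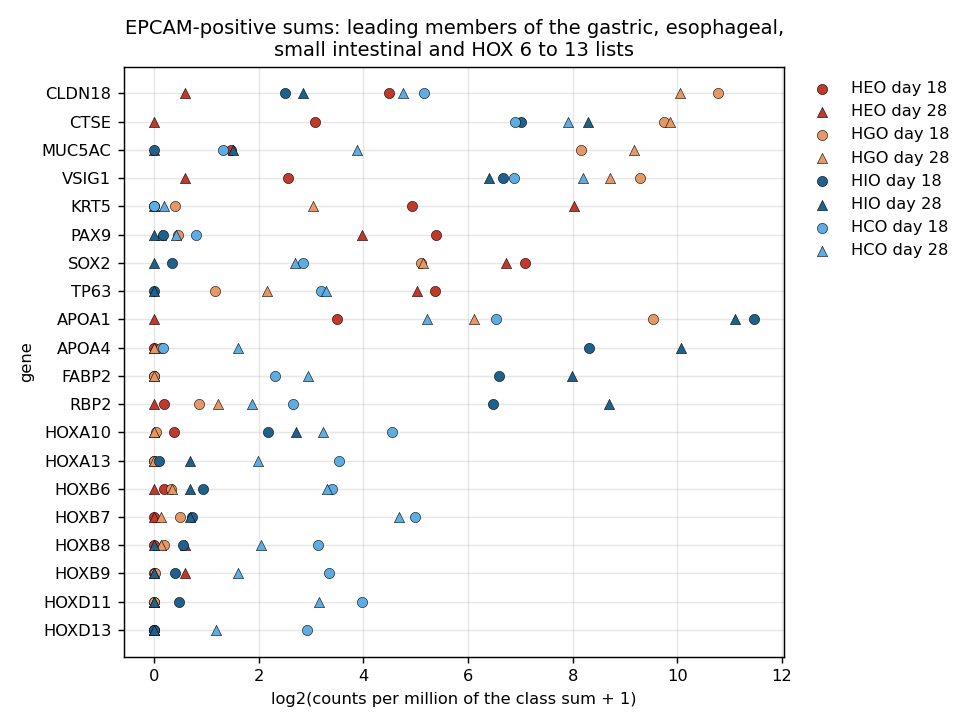
Dots give log2(CPM + 1) of the EPCAM-positive sum in each library for leading genes of the gastric, esophageal, small intestinal and HOX 6 to 13 lists, colours mark organoid type, circles day 18 and triangles day 28. CLDN18 is highest in HGO (1748 and 1057 CPM) and APOA4 in HIO (317 and 1075 CPM).

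Other lists were compared between HGO and HEO. Of 15 small intestinal genes, 7 were higher in HGO, such as FABP1 (8.86 ± 0.68), VIL1 (4.89 ± 0.28) and PDX1 (4.94 ± 0.51), with the same count adjusted over the list alone (0.000109, and adjusted p = 0.23 with an estimated correlation). Of 14 dissociation stress genes, 10 were higher in HGO, such as FOS (2.04 ± 0.30) and DUSP1 (2.56 ± 0.27), with the same count over the list alone (0.000109, and adjusted p = 0.342 with an estimated correlation). Of 12 WNT response genes, 7 were lower in HGO, such as LEF1 (-5.47 ± 0.43) and ZNRF3 (-2.27 ± 0.28), with the same count over the list alone (0.00325, and adjusted p = 0.23 with an estimated correlation). Of 12 retinoic acid genes, 7 were lower, such as the binding proteins CRABP1 (-5.67 ± 0.67) and CRABP2 (-4.25 ± 0.42), and 2 higher, DHRS3 and ALDH1A1 (5.32 ± 0.40), with the same counts over the list alone (0.044, and adjusted p = 0.23 with an estimated correlation). DHRS3 was outside the naming rule and chosen after its value was seen. Of 3 tested lung genes, SCGB3A2 was lower in HGO (list adjusted p = 0.881), a call lost without HEO (0.281) or HGO (0.157) at day 18. The neuronal gene STMN2 (-11.01 ± 0.49) was lower in HGO. Mesenchyme markers moved with these. COL3A1 stood at 171 and 275 CPM in the EPCAM-positive sums of HEO and at 7.44 and 9.94 in those of HGO.

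In total 3366 genes were higher in HGO and 3062 in HEO of 17613 (edgeR, 2 libraries each), and DESeq2 called 3206 and 3350. The genes named here with a fold change passed in every leave-out. The total of 6428 was 3630 without HEO at day 18, 3352 without HGO at day 18 and 3556 with sums thinned to the smallest, which holds the 209 HEO cells of day 28.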

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

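The search for libraries far from the other 3 of their region was planned, and no test was added after its results were seen. Among like libraries with normally spread values, chance alone would mark about 1 in 20 groups, and 6 of the 52 groups searched were marked. The libraries of a region differ in organoid type and day, so that rate is only a rough guide. A difference between types or days can mark a library too. All 6 concern CPM in mesenchyme-like sums.

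DLK1 stood at 296 CPM in HEO at day 28, against 42.3 to 81.6 in the other foregut libraries. HOXA10 stood at 2.04 CPM in the same library, against 0.0941 to 0.317. PRG4 was at 73.0 CPM in HGO at day 28, against 2.79 to 14.2 in the other foregut libraries. DGKB was at 1.10 CPM in HEO at day 18, below the 2.28 to 2.45 of the other foregut libraries. Among the hindgut libraries, OLFML2B was at 6.43 CPM in HCO at day 28, against 3.79 to 4.19. S100B was at 1.40 CPM in HCO at day 18, against 0.145 to 0.277.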

How the results depend on the processing

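The tests with whole UMIs and with both libraries of an organoid type left out were chosen after the result was seen. Neither DESeq2, its size factors nor any leave-out of 1 library turned the direction of a named gene that had passed the threshold (250 calls). Genes that pass seldom turn, and named genes that did not pass were not checked. The mesenchyme-like share kept its day difference positive in all alternatives and leave-outs (12.6 to 29.5 points), while the region difference ranged from -20.7 to 8.12 points and turned positive without HEO at day 18 (2.43) or 28 (3.74) or HCO at day 18 (8.12) or 28 (1.71). The causes of the changes below were not tested. Leaving out 1 library gave 118 to 497 called genes for mesenchyme-like region (617 in full), 0 to 14 for day (9), 7 to 1081 for HCO against HIO (1307), and 16 to 241 for HGO against HEO (157). In EPCAM-positive sums the ranges were 0 to 2 for region (9), 1 to 313 for day (94), 204 to 2611 for HCO against HIO (2336) and 3352 to 6716 for HGO against HEO (6428). The DESeq2 Wald test called 2196, 1129, 2756 and 939 genes in mesenchyme-like sums in that order, 768 for region and 1005 for day in EPCAM-positive sums, and 1 for each region by day term. Summing all cells of a library gave 1, 2, 1990 and 3065 in place of the mesenchyme-like counts, and 1 for region, 2 for day and 3065 for HGO against HEO in place of the EPCAM-positive ones. Of the other alternatives outside 1.5 times, mesenchyme-like day counts were 1 at resolution 2, 211 with no low-count filter, 59 thinned, 19 with genes listed in all libraries and 22 with whole UMIs. Mesenchyme-like HGO against HEO was 261 with each library clustered alone and 385 with no filter. EPCAM-positive region was 4 under the stricter cell filter, 0 at resolution 2 and with each library clustered alone, 18 with no filter and 17 thinned. EPCAM-positive day was 0 under the stricter filter and with each library clustered alone, 5 with doublets kept, 151 at resolution 2, 1028 with no filter, 199 thinned and 187 with genes listed in all libraries. EPCAM-positive HCO against HIO was 1173 with each library clustered alone and 1169 thinned, and HGO against HEO 3556 thinned. Without both HEO, HGO, HIO or HCO libraries, mesenchyme-like region was 46, 354, 968 and 377, EPCAM-positive region 17, 2341, 0 and 3 and EPCAM-positive day 0, 7, 1 and 225, while mesenchyme-like day was 0, 2 and 1 without HEO, HGO and HCO. Of 128 list tests outside the region by day term, 61 passed at the preset correlation, 1 with an estimated one and 15 with fry. Of 250 named calls, DESeq2 kept 237 and its size factors in edgeR 246, and leave-outs ended from 70 (HCO day 28) to 144 (HIO day 18). The EPCAM-positive sums of HEO and HIO at day 28 were the smallest, at 1.48 and 1.85 M counts.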

Other observations

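Tests chosen only after the result was seen were those on RNA from EPCAM-positive cells, on the cell filter, on cycling, on folds after thinning, on other splits of the libraries and with whole UMIs.

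Some changes were seen within a single organoid type between days 18 and 28, where 1 library per day allows no test. In HEO mesenchyme-like sums the calcification inhibitor MGP went from 506 CPM (95% Poisson interval 500 to 513) to 5574 (5553 to 5595) and clusterin, CLU, from 15.8 (14.6 to 17.0) to 228 (224 to 232). MGP in HIO went from 47.4 CPM (45.3 to 49.5) to 1024 (1016 to 1032), and the complement gene C7 in HGO from 29.6 (26.3 to 33.2) to 473 (462 to 483). The cartilage collagen COL2A1 was lower at day 28 in both foregut types, at 269 and 37.0 CPM in HEO and 233 and 18.0 in HGO. Cartilage-like cells, which are not part of these sums, were 0.292% and 1.10% of HEO cells and 7.19% and 0.794% of HGO cells at these days. In HIO the hedgehog target HHIP went from 212 to 52.0 CPM and the noncoding RNA FENDRR from 118 to 26.3. In HCO the inhibitor heavy chain gene ITIH5 went from 13.8 to 225 CPM, and the neuropeptide gene TAC1 from 107 to 22.0.

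In EPCAM-positive sums of HEO the calprotectin subunit S100A8 went from 6.46 CPM (4.47 to 9.03) to 961 (911 to 1012), and the suprabasal keratin KRT13 from 3 counts, or 0.570 CPM (0.118 to 1.67), to 236 (212 to 262). SPINK1 and TFF2, a gastric trefoil factor, went from 196 and 123 CPM to 1 and 0 counts. In HGO the vitamin B12 carrier TCN1 went from 48.1 to 344 CPM, while MSMB went from 13441 to 3582 and APOA1 from 642 to 64.5. In HIO the guanylin genes GUCA2A (10.7 to 185 CPM) and GUCA2B (22.8 to 361) were higher at day 28, and TOP2A (241 to 57.4) and MKI67 (118 to 31.9) lower. In HCO the stress cytokine GDF15 went from 25.7 to 159 CPM, and the sulfate transporter SLC26A2 from 169 to 22.2.

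Genes of HOX groups 1 to 5 were higher in HGO than in HEO mesenchyme-like sums, 9 of 13 of them past the threshold. HEO at day 18 lacked 4.42% of its counts relative to values rounded up to whole UMIs, as after a background subtraction. With whole UMIs 9 of the 13 were still called, which argues against partly subtracted counts as the cause. Counts removed entirely cannot be restored by rounding up, so their loss stays open. RNA from EPCAM-positive HGO cells is argued against too, since the log2 ratio of mesenchyme-like to EPCAM-positive CPM had a lower quartile of 2.40 over the genes in the HGO library where it was lowest. The longer retinoic acid treatment of HGO spheroids, a difference the labels give, stays open and untested, since treatment, organoid type and any batch coincide. A test would need 1 organoid type grown with and without it.

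The mesenchyme-like share was higher at day 28 in 4 of 4 organoid types. The smallest of the 4 differences was 4.03 points or more with doublets kept or under the stricter filter. That argues against the cell filter and doublet removal used here as the cause. Any filter set before deposit stays open, since barcodes it removed cannot be restored. In HGO the largest number of genes per deposited barcode was 7490 at day 18 and 6009 at day 28. More cycling in mesenchyme-like than in EPCAM-positive cells may contribute. In 3 of 4 day 18 libraries the summed CPM of the G2 and M list was higher in mesenchyme-like sums (2900 against 2035 in HEO, 3817 against 1616 in HGO and 3557 against 1313 in HIO), but in HCO it was 1606 against 1661, so this cannot be told apart from other causes. Loss of EPCAM-positive cells during dissociation, and true growth of the mesenchyme with time, stay open and untested.

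For the 58 genes called higher at day 28 in EPCAM-positive sums, free RNA from mesenchyme-like cells is argued against for the set as a whole, since the median log2 ratio of their mesenchyme-like to EPCAM-positive CPM at day 28 was -2.10 (quartiles -4.23 and -0.57). For 8 of the 58, with a ratio above 1, it stays open and may account for the call. Thinned to the smallest sum, 69.0% (40 of 58) were still called, so these 40 passed with all sums at like depth. Over the 50 still tested the ratio of thinned to full log2 fold change had a lower quartile of 0.898 (lowest 0.685). Random thinning keeps folds on average by construction, so this ratio cannot decide whether shallower day 28 sums made the calls. The 10 tested genes that lost the call had a median log2 fold change of 1.20 in full and 1.02 in thinned sums, with a median SE of 0.18 and 0.30, so their error widened more than their folds shrank. For the genes not still called, including 8 that fell under the low-count filter, depth cannot be told apart from a change with time. Maturation of the epithelium was not tested.

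Other splits of the 8 libraries into 4 and 4, of which the models could be fitted to 34 for region and 32 for day, were run. In mesenchyme-like sums 1 of 34 splits gave as many genes as the region split (617, highest other 0) and 1 of 32 as the day split (9, highest other 0), the real ones. For the EPCAM-positive day split it was 1 of 32 (94 genes, highest other 0). The other splits mostly mix the organoid types, and those that respect them, 3 that keep each type whole for region and 8 that part the days of every type, are too few for a share under 0.05. For the EPCAM-positive region split chance is not excluded, since 3 of 34 splits gave as many as its 9 genes (highest other 158). HEO with HCO against HGO with HIO gave 158 and HEO with HIO against HGO with HCO gave 27, which points to a structure of the libraries other than region.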
